A study of Mus musculus with 35 samples.

How the data were processed

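Polyadenylated RNA of mouse colon tumour organoids grown in vitro was measured in 35 libraries. Per the labels' protocols, RNA was extracted with TRIzol and PureLink columns and made into strand-specific libraries after poly(A) selection. The estimated counts per gene were deposited by the authors as a single table of whole numbers, made with Salmon 1.3.0 against mm10 per the submitters' processing notes. The annotation release, the read length and the step from transcripts to genes are not given in the sources used here. The table holds 54354 genes, of which 1243 have no name and hold 0.0216% of the counts, and 883 symbols stand for more than 1 gene. Gene positions and types were taken from GENCODE M21, which holds 51485 of the gene identifiers. All value columns belong to listed libraries, and no 2 columns are identical. Over the 178 pairs of libraries within groups, the lowest chi-square per degree of freedom was 7.87 and the median 41.4, where counting error alone would give 1.

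Groups were taken from the labels: palmitic acid controls (3 libraries), palmitic acid batch 1 (3), palmitic acid batch 2 (2), carmofur controls (12) and carmofur (15). The labels name 1 control group for palmitic acid, assigned to neither batch, so both batches were compared with it. Library numbers of the carmofur experiment fall into 9 sets of 3 consecutive numbers and 3 blocks of 12 numbers. These sets and blocks were defined from the labels and are not stated there to be batches.

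Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default expression filter, robust dispersion estimation and the quasi-likelihood F test. Benjamini-Hochberg adjustment was made over all genes tested, at a threshold of 0.05. The palmitic acid libraries were fitted together (8 libraries, 9845 genes tested), the carmofur libraries together (27, 9992) and all 35 together for the difference of the effects (14052). The biological coefficients of variation were 0.41, 0.75 and 0.97. The standard error of a log2 fold change is its size divided by the square root of F. CPM are TMM-scaled. The floor for a count of 0 is 3 counts. On simulated data with these depths and this spread, the tests found 18.6% of 2-fold and 45.3% of 4-fold changes for palmitic acid batch 1, 12.9% and 41.2% for batch 2, 16.5% and 53.8% between batches, 43.9% and 62.4% for carmofur, and 0% and 19.8% for the difference. In the same simulations 11.3%, 3.64%, 1.52% and 2.70% of the calls in the first 4 comparisons were of genes simulated without a change.

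The comparisons, their tests, 37 gene lists, the genes fixed by name and the rule for naming genes were chosen before the data were examined. The rule names the 8 largest rises and falls among genes past the threshold with a mean of at least 5 CPM and a consistent direction, leaving out unnamed and predicted genes and pseudogenes. For palmitic acid the direction counted as consistent where every treated library lay beyond every control, and for carmofur where at least 12 of 15 lay beyond the control median. It also names up to 4 members with the lowest p of each list described, and the genes fixed by name. Some of the genes it names are not reported here. For batch 2 and for the difference of the effects it names these and the 3 largest rises and falls. Lists with at least 5 tested members were tested with camera on limma 3.58.1 voom values, with an inter-gene correlation of 0.01 and, as an alternative, with the estimated correlation. The members past the threshold were counted both over all genes and adjusted over the list alone.

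Correlations between treatments were Pearson's r over genes tested in both fits. For the palmitic acid batches, which share controls, unchanged treated groups were simulated 100 times against the same controls. Labels were also exchanged: all 10 splits of the 6 control and batch 1 libraries, 100 splits of the carmofur libraries and of the library sets, and 60 splits drawn within both experiments. Chosen after the count of the difference was seen were 100 splits of the library sets and palmitic acid libraries together, and all 20 arrangements of the palmitic acid labels with the carmofur labels kept.

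Alternatives fixed beforehand were RLE size factors in edgeR, the test of DESeq2 1.42.0 and limma-voom with quality weights. Also fixed beforehand were no filter, a filter at a mean count of 10 and a minimum absolute log2 fold change of 1. So were each library or library set left out, the replicate number as a block, and palmitic acid batches merged. The last of these were library sets summed or as a correlated group, and library blocks as a covariate. Chosen after the data were seen were fits without 3 libraries that stood apart in principal components (carmofur control 1 and carmofur 8 and 10), the palmitic acid lists without its shallow control 1, offsets for transcript length and GC content, and library-size scaling. The offsets were first written so that they also recentred each library, and were corrected after that output was seen to remove the trend alone. The code was tested on simulated data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.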

Results

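RNA was sequenced from mouse colon tumour organoids, self-organised epithelial cultures, whose genotype is labelled AKP. The organoids were grown in vitro with palmitic acid, a saturated fatty acid that cells use to build ceramides, or with carmofur, an inhibitor of ceramidases that is also known as a prodrug of a fluorinated pyrimidine. The stated question was how fatty acid and ceramide levels alter the organoid transcriptome. The palmitic acid experiment held 3 control libraries, 3 treated libraries of batch 1 and 2 treated libraries of batch 2. The labels assign the controls to neither batch. The carmofur experiment held 12 control and 15 treated libraries. Total gene counts per library ranged from 762888 to 2511723 in the palmitic acid controls, 2138905 to 2845017 in batch 1 and 2406582 to 3742289 in batch 2. They ranged from 1663750 to 8124707 in the carmofur controls and 3127275 to 10609563 with carmofur. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The PCR reads carry no molecular identifiers, so the limit set by a count of 0 covers counting error only. That limit is 3 counts, or 0.283 CPM in the deepest library and 3.93 CPM in the shallowest.

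Tff1 and Wfdc18 rose and Rnf186, Fgfbp1 and Car1 fell with palmitic acid in batch 1. Tff1, a trefoil peptide of mucus-secreting epithelium (ENSMUSG00000024032; mm10 chromosome 17, 31161395 to 31165277), rose from 0.58 ± 0.694 to 24.8 ± 18.1 CPM (mean ± SD, n = 3 each). Its log2 fold change was 5.03 ± 0.83 (SE; adjusted p = 4.11e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all single-gene values here). Wfdc18, a secreted protein with a whey acidic protein domain (chromosome 11, 83709015 to 83711348), rose from 2.54 ± 2.31 to 28.3 ± 6.7 CPM, a log2 fold change of 3.19 ± 0.55 (adjusted p = 9.08e-05). In the opposite direction, Rnf186, an E3 ubiquitin ligase of the gut epithelium (chromosome 4, 138967112 to 138968360), fell from 154 ± 7.25 to 57.4 ± 12.9 CPM, and Fgfbp1, a carrier of fibroblast growth factors (chromosome 5, 43978858 to 43981779), fell from 196 ± 18.5 to 73.8 ± 22.3 CPM. Their log2 fold changes were -1.42 ± 0.23 (adjusted p = 2.08e-05) and -1.40 ± 0.21 (adjusted p = 5.96e-06). Car1, a carbonic anhydrase of colonocytes (chromosome 3, 14766216 to 14808368), fell from 524 ± 25.7 to 259 ± 7.89 CPM, a log2 fold change of -1.02 ± 0.14 (adjusted p = 6.09e-07).

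The other large rises were those of the hair keratins Krt32 (log2 fold change 4.04) and Krt33a (2.12), the growth factor Ptn (2.16), the muscle genes Smpx (1.95) and Tnni1 (1.69), and the chemokine Cxcl15 (1.90). Their adjusted p-values ran from 0.00382 for Tnni1 to 0.0473 for Cxcl15. The other large falls were those of the lipid transfer protein gene Vps13c (-4.09), Mgat4c (-2.03), the actin-membrane linker moesin (Msn, -1.35), the chymase Cma1 (-1.33) and Serpinb11 (-0.98), with adjusted p-values from 0.00142 for Cma1 to 0.0332 for Vps13c. In each of these genes every treated library lay beyond every control, as the naming rule asks. Krt32 went from 0.841 ± 0.422 CPM in the controls to 13.1 ± 15.7 CPM in batch 1, and Vps13c from 17.8 ± 15.4 to 0.962 ± 0.1 CPM. The lower level of each lay near or under the limit of 3 counts (1.19 to 3.93 CPM in the controls, 1.05 to 1.4 CPM in batch 1). The sizes of these changes are therefore uncertain. So are those of Tff1 and Wfdc18, which lay at 0 to 1.35 and 0 to 4.5 CPM in the controls. In total 55 of the 9845 genes tested passed an adjusted p of 0.05, 31 higher and 24 lower (n = 3 against 3). Without control replicate 1, the shallowest library, the calls of Cma1, Cxcl15, Krt32, Krt33a, Mgat4c, Msn, Ptn and Smpx were lost. Without batch 1 replicate 3 the total was 21 genes and 12 of the 17 named calls were lost, while Car1, Fgfbp1, Rnf186, Tff1 and Wfdc18 passed whichever library was left out. With limma-voom and quality weights the calls of Tff1, Wfdc18, Cxcl15, Krt32, Krt33a, Ptn, Smpx and Vps13c were lost. With both batches as 1 group those of Car1, Cma1 and Serpinb11 were lost, and with the replicate number as a block those of Cxcl15, Krt32, Krt33a, Serpinb11, Smpx, Vps13c and Nupr1, a gene described below. Cxcl15 was also lost with DESeq2, a higher filter, library-size scaling or offsets for length and GC content, Smpx with that filter or the offsets, Vps13c with the offsets and Serpinb11 without a filter.

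**Figure D1:**
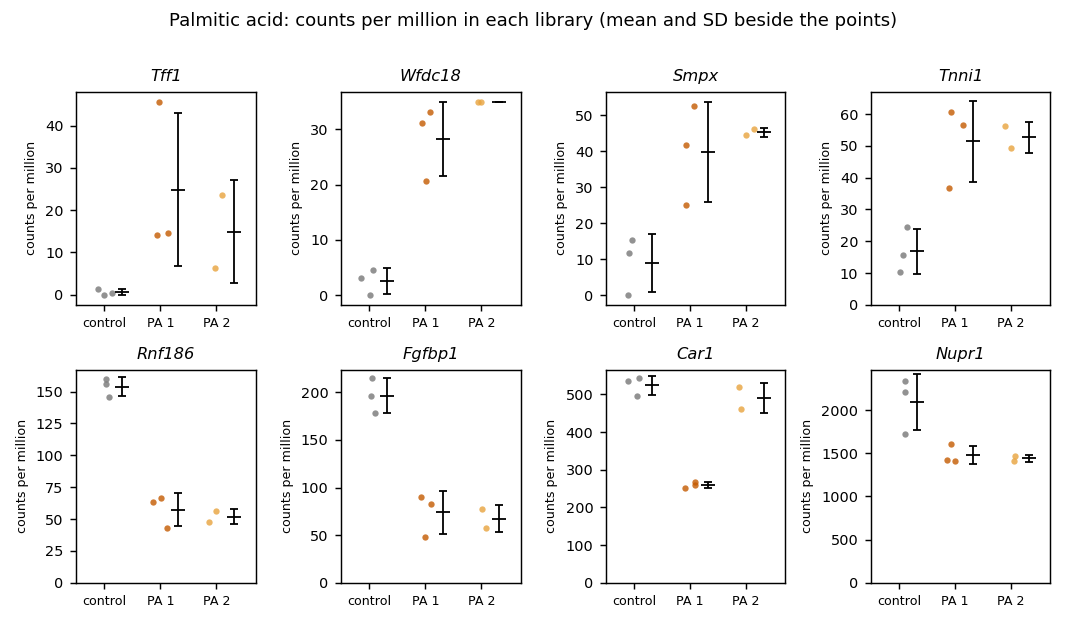
Expression of genes named for palmitic acid, in TMM-scaled CPM on the vertical axes, per library of the control, batch 1 and batch 2 groups; points are libraries and bars give the mean ± SD. Rnf186 lies near 154 CPM in the controls and 57.4 CPM in batch 1, whereas Car1 falls to 259 CPM in batch 1 and is at 490 CPM in batch 2.

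Among the gene lists, markers of absorptive colonocytes were lower with palmitic acid in batch 1. Car1 fell, 1 of 10 measured members (2 adjusted over the list alone). The list's median log2 fold change was -0.41, and camera gave an adjusted p of 0.000457 (adjusted p = 0.133 with an estimated correlation). In batch 2 the list did not pass, with a median of -0.11 (camera adjusted p = 0.0956) and 0 members past the threshold over all genes. In batch 1 Car2, the major cytosolic carbonic anhydrase of the colon, had a log2 fold change of -0.37 ± 0.11 that did not pass (adjusted p = 0.107). The brush-border gene Vil1 did not pass there either (-0.31, adjusted p = 0.82). In the integrated stress response list of ATF4 and CHOP targets, 1 of 31 members fell (3 adjusted over the list alone). This was Nupr1, a stress-induced chromatin protein, at -0.50 ± 0.12 (adjusted p = 0.0143). That list's median was -0.25 (camera adjusted p = 0.0014, adjusted p = 0.133 with an estimated correlation). The call of Nupr1 was lost without control replicate 2 or 3 or batch 1 replicate 1 or 3. For nuclear-encoded oxidative phosphorylation, 0 of 39 members passed by edgeR over all genes or adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.00217, adjusted p = 0.424 with an estimated correlation). Its members with the lowest p were Atp5d (0.48, adjusted p = 0.188), Uqcrc1 (0.999, 0.418) and Cox5b (0.51, 0.44).

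The lists closest to the treatment did not pass. In sphingolipid and ceramide metabolism 0 of 31 members passed over all genes or adjusted over the list alone (median 0.26, camera adjusted p = 0.376). Its members with the lowest p were Ormdl1, Sptssa, Sgpl1 and Sptlc2. Ormdl1, a regulator of serine palmitoyltransferase, had a log2 fold change of 0.74 ± 0.24 (adjusted p = 0.205). Sptssa, a subunit of that enzyme, was at 0.36 (0.569), and Sptlc2, a catalytic subunit of the same enzyme, at -0.66 (0.613). The sphingosine phosphate lyase gene Sgpl1 was at 1.35 ± 0.61 (0.578). In fatty acid oxidation and PPAR targets 0 of 20 passed either way (median 0.06, camera adjusted p = 0.506). The lipid droplet coat gene Plin2 had a log2 fold change of 0.28 (adjusted p = 0.711) and the carnitine transferase gene Cpt1a -0.10 (0.995). The acid ceramidase gene Asah1 had a log2 fold change of 0.10 ± 0.16 (adjusted p = 0.962). Of genes that are often engineered in colon tumour organoids, Apc (-0.03) and Trp53 (0.95) did not pass. The stem cell genes Lgr5 (0.46), Ascl2 (-0.03), Clu (0.96), Anxa1 (-0.13), Ly6a (-0.35, adjusted p = 0.196) and Cd44 (-0.19) did not pass either, and neither did the ceramidases Acer2 (0.27) and Acer3 (-0.28) or Myc (-0.11).

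In the remaining lists tested with camera in batch 1 the adjusted p ranged from 0.0605 to 0.949. Cholesterol biosynthesis had 1 of 25 members up (Fdps, 2 adjusted over the list alone, list adjusted p = 0.0605) and hypoxia and glycolysis 2 of 32 down (Pfkp and Ero1a, 3 adjusted over the list alone, 0.0675). Paneth cell markers had 1 of 7 down (Nupr1, 2 up and 1 down adjusted over the list alone, 0.0701), and goblet cell markers 1 of 10 up (Tff1, 2 up and 1 down adjusted over the list alone, 0.248). ER chaperones had 1 of 28 down (Hspa5, 1 adjusted over the list alone, 0.0992), NRF2 and antioxidant genes 1 of 32 up (Mt2, 2 adjusted over the list alone, 0.474) and lysosome genes 1 of 35 up (Lamp2, 1 adjusted over the list alone, 0.276). In the other lists no member passed over all genes, and the brackets that follow give the list's adjusted p and any number that passed adjusted over the list alone. For cell state these were revival and fetal-like stem markers (0.377), crypt-base columnar markers (0.472, 1 down), YAP targets (0.406) and epithelial-mesenchymal transition (0.406). For growth and metabolism they were fatty acid synthesis (0.949), p53 targets (0.664), S phase (0.135), G2/M (0.135), DNA repair (0.949), ribosome biogenesis (0.336), nucleotide synthesis (0.0992) and ribosomal proteins (0.0728). For signalling and stress they were interferon-stimulated genes (0.949), NF-kB genes (0.949), MAPK feedback genes (0.531), heat shock (0.144) and apoptosis (0.949, 1 up). The last were mitochondrial mRNAs (0.883, 1 down), replication-dependent histones (0.406, 1 down) and the genes fixed by name (0.918, 1 down). The summed markers of other cell types were 32.1 ± 5.53 CPM in controls and 28.2 ± 5.94 CPM in batch 1 for mesenchymal genes, 128 ± 18.3 and 108 ± 32 CPM for immune genes, and 14.4 ± 1.42 and 15.3 ± 3.84 CPM for endothelial and blood genes. These lists and the enteroendocrine and tuft cell lists had fewer than 5 tested members.

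In batch 2, compared with the same controls, Tff1 and Wfdc18 rose again, with log2 fold changes of 4.32 ± 0.86 (adjusted p = 0.00266, n = 2 against 3, edgeR) and 3.5 ± 0.57 (adjusted p = 5.47e-05). Rhoj had 0 counts in the controls and in batch 1 and 77 counts in batch 2, at least 23.5-fold higher than the 0.544 CPM that 3 counts over the controls would give. The gap junction gene Gja1 fell (-5.49, adjusted p = 0.0209), as did the linker histone gene H1f5 (-2.34, 0.0236) and Msn (-1.63, 0.0082). Gja1 lay at 0 to 0.416 CPM in batch 2, under the limit of 3 counts there (0.802 and 1.25 CPM). The size of its change is uncertain, as are those of Tff1 and Wfdc18, which were low in the controls. In total 32 genes passed, 18 higher and 14 lower. Since the controls belong to no stated batch, batch and treatment cannot be told apart in this contrast or in that of batch 1. Of the 6 named calls only Wfdc18 was kept without each library in turn. Tff1 was lost without batch 2 replicate 1, Msn without control replicate 1 or either batch 2 replicate, H1f5 without control replicate 1 or any treated library of either batch, Gja1 without control replicate 3 or any treated library of either batch, and Rhoj without whichever library was left out. With limma-voom and quality weights only Msn of the 6 was kept, and with the replicate number as a block Gja1, H1f5 and Rhoj were lost.

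The batches differed directly in 10 of 9845 genes, 6 higher and 4 lower in batch 2. The total was 5, 6 and 2 genes without batch 1 replicate 1, 2 and 3. Car1 was 0.92 ± 0.15 log2 units higher in batch 2 than in batch 1 (adjusted p = 0.000165), at 490 CPM over 2 libraries against 259 ± 7.89 CPM over 3. Cma1 was 1.31 ± 0.20 higher (adjusted p = 0.0122), while the metallothionein Mt4 (-0.80 ± 0.14, adjusted p = 0.000771) and the pseudogene Rps23-ps1 (-0.79 ± 0.17, 0.0184) were lower. The other 6 genes were near 0 CPM in 1 batch. Among them Rpl31-ps9, Lce6a, Ceacam2 and Gm11571 were higher in batch 2, and Ang4 and Gja1 lower. Only Car1 and Rpl31-ps9 passed whichever library was left out. Cma1 was lost without control replicate 1 or 3 or batch 1 replicate 3, and Mt4 without batch 1 replicate 3 or batch 2 replicate 2. Rps23-ps1 was lost without control replicate 1, batch 1 replicate 1 or 3, or either batch 2 library. Ang4, Gja1 and Lce6a were lost without any 1 treated library, Ceacam2 without any batch 1 library or batch 2 replicate 1, and Gm11571 without batch 1 replicate 1 or 3 or batch 2 replicate 1. These genes, apart from Car1, Cma1, Gja1 and Mt4, were named after their values were seen. Mt4, both pseudogenes, Ceacam2 and Ang4 have relatives of similar sequence, so the division of reads among them is uncertain. Between the batches 25 genes passed in both comparisons with the controls, 14 higher in both, 10 lower in both and 1 in opposite directions. The comparisons share their controls, and no value of this overlap for unchanged groups was computed. The log2 fold changes correlated across genes with r = 0.616, where unchanged groups simulated against the same controls gave 0.477 (0.448 to 0.505, 100 simulations). The covariance was 0.442 against 0.268 (0.242 to 0.293). The 3 controls are too few to divide between the batches.

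The batch 2 lists past an adjusted p of 0.05 by camera that were lower were G2/M (median -0.36, camera adjusted p = 1.41e-07, adjusted p = 0.0415 with an estimated correlation), hypoxia and glycolysis (-0.27, 1.39e-05, adjusted p = 0.185 with an estimated correlation) and the integrated stress response (-0.32, 0.000338, adjusted p = 0.106 with an estimated correlation). Those that were higher were ribosome biogenesis (0.20, 0.000962, adjusted p = 0.224 with an estimated correlation), oxidative phosphorylation (0.09, 0.0291, adjusted p = 0.492 with an estimated correlation), lysosome (0.17, 0.0291, adjusted p = 0.185 with an estimated correlation) and heat shock genes (0.29, 0.0291, adjusted p = 0.224 with an estimated correlation). Single members passed over all genes in the stress response (1 of 31 down, 2 adjusted over the list alone) and in hypoxia and glycolysis (1 of 32 down, 3 adjusted over the list alone), and 0 of 39 in G2/M (4 down adjusted over the list alone). In ribosome biogenesis, oxidative phosphorylation, lysosome and heat shock genes 0 members passed over all genes, and adjusted over the list alone 1 lysosome gene was higher. The other lists had camera adjusted p-values from 0.0832 to 0.991.

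With carmofur the integrated stress response, ER chaperone and ribosomal protein lists were lower, with the tests given below. Asns, asparagine synthetase (ENSMUSG00000029752; mm10 chromosome 6, 7675169 to 7693254), fell 2.88-fold, from 708 ± 120 CPM in 12 controls to 245 ± 70.2 CPM in 15 treated libraries (mean ± SD). Its log2 fold change was -1.53 ± 0.12 (adjusted p = 4.46e-11, edgeR). Hspa5, the ER chaperone BiP (chromosome 2, 34771970 to 34777547), fell from 750 ± 189 to 322 ± 70.8 CPM (-1.22 ± 0.12, adjusted p = 1.76e-09). Rpl3, a protein of the large ribosomal subunit (chromosome 15, 80077791 to 80091868), fell from 5150 ± 472 to 2990 ± 413 CPM (-0.79 ± 0.06, adjusted p = 4.46e-11). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), rose from 78.8 ± 54.1 to 553 ± 303 CPM (2.83 ± 0.34, adjusted p = 9.11e-07). In each of these 4 genes all 15 treated libraries lay beyond all 12 controls. In total 901 of 9992 genes passed, 521 higher and 380 lower. The library numbers fall into 9 sets of 3 consecutive numbers, each of 1 group, and the calls lost without a set or with counts summed by set are named below. With counts summed by set (4 sets against 5), 334 genes passed.

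The integrated stress response list fell as a group: 14 of 31 measured members fell (20 adjusted over the list alone) and none rose, with a median log2 fold change of -0.78 (camera adjusted p = 6.44e-18). Besides Asns these included the serine synthesis enzyme Psph (-1.13 ± 0.15), the mitochondrial phosphoenolpyruvate carboxykinase Pck2 (-1.09 ± 0.17), the seryl-tRNA synthetase Sars (-0.73 ± 0.11) and the pseudokinase Trib3 (-1.79 ± 0.58, adjusted p = 0.0412, lost without library set 1, 4, 5, 7, 8, 11 or 12). Of 28 ER chaperone and XBP1 or ATF6 target genes, 9 fell (13 adjusted over the list alone), median -0.51 (camera adjusted p = 2.96e-11), with Pdia6 at -0.66, Hsp90b1 at -0.56 and Pdia4 at -0.49. Of 44 cytosolic ribosomal protein genes, 31 fell (35 adjusted over the list alone), median -0.28 (camera adjusted p = 1.15e-31), with Rpl10a at -0.64, Rps18 at -0.48 and Rpl32 at -0.43. With sets summed, the ribosomal list had an adjusted p = 0.175 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, so the division of their reads is uncertain. The paralogue Rpl22l1, outside that list, fell from 593 ± 98.1 to 213 ± 76.1 CPM (-1.48 ± 0.14, adjusted p = 2.65e-09). In hypoxia and glycolysis 10 of 32 fell (16 adjusted over the list alone), median -0.41 (camera adjusted p = 2.15e-11, adjusted p = 0.0471 with an estimated correlation, and 0.214 with sets summed). The platelet phosphofructokinase Pfkp was at -0.76, Gapdh at -0.51, Tpi1 at -0.50 and the hypoxia-induced Ndrg1 at -1.01. In nuclear-encoded oxidative phosphorylation 6 of 39 fell and 1 rose (the same numbers adjusted over the list alone), median -0.13 (camera adjusted p = 0.00153, adjusted p = 0.0674 with an estimated correlation). Those that fell included Uqcrc2 (-0.52), Atp5c1 (-0.39), Ndufb5 (-0.39) and Uqcrq (-0.28). With sets summed the calls of Trib3, Hsp90b1, Gapdh, Uqcrc2, Atp5c1, Ndufb5 and Uqcrq were lost.

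Markers of regenerating and fetal-like intestinal epithelium, the revival stem list, were higher with carmofur: 13 of 23 rose (18 adjusted over the list alone) and none fell, median 0.62 (camera adjusted p = 1.08e-14). With sets summed, the list had an adjusted p = 0.0774 with an estimated correlation. Clu, the secreted chaperone clusterin that marks revival stem cells (chromosome 14, 65968483 to 65981547), rose from 12.4 ± 12.5 to 93 ± 46.5 CPM, 7.57-fold (2.92 ± 0.49, adjusted p = 7.31e-05), and the alarmin Il33 from 14.8 ± 8.60 to 52.5 ± 14.2 CPM (1.85 ± 0.27, adjusted p = 3.3e-06). The interleukin-1 receptor antagonist Il1rn (1.13 ± 0.13) and the hyaluronan receptor Cd44 (0.91 ± 0.14) also rose. Ly6a, whose Sca-1 protein marks fetal-like epithelium and which belongs to a family of similar genes, had a log2 fold change of 0.25 ± 0.08 (adjusted p = 0.0433). This call was lost without library set 1, 5, 8 or 9 and with the libraries summed by set (adjusted p = 0.37), and Anxa1 had 0.20 ± 0.09 (adjusted p = 0.184). In the crypt-base columnar list 3 of 19 fell and 2 rose (the same adjusted over the list alone), median -0.51 (camera adjusted p = 0.0312, adjusted p = 0.0842 with an estimated correlation). The members that fell were the stem cell regulator Lrig1 (-1.75 ± 0.38, adjusted p = 0.00133), the transcription factor Ascl2 (-1.21 ± 0.39, adjusted p = 0.0417) and Cdca7 (-0.66), and those that rose were Cd44 and Prom1 (0.51). The calls were lost without library set 1, 3, 4, 8, 9, 11 or 12 (Ascl2), 5, 8 or 12 (Cdca7) and 1, 5, 8, 9 or 11 (Prom1), and all 3 with sets summed. Lgr5 had a log2 fold change of -0.76 ± 0.53 (adjusted p = 0.505).

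The lists of absorptive, invasion and mitosis genes were also higher with carmofur. In absorptive colonocyte markers 5 of 10 rose (5 adjusted over the list alone), median 0.83 (camera adjusted p = 5.3e-05). With sets summed, the adjusted p with an estimated correlation was 0.0774 for this list, 0.134 for invasion, 0.175 for G2/M and 0.188 for NF-kB genes. The keratin Krt20 rose from 4.24 ± 4.15 to 30.5 ± 10.1 CPM (2.82 ± 0.51, adjusted p = 0.000101), and Car2 by 0.65 ± 0.07 (adjusted p = 3.85e-09). Emp1 (0.62), the brush-border gene Cdhr2 and Car1 also rose, Car1 from 420 ± 172 to 841 ± 431 CPM (adjusted p = 0.0119, lost without library set 5, 11 or 12). In epithelial-mesenchymal transition and invasion 10 of 20 rose (12 adjusted over the list alone), median 0.83 (camera adjusted p = 2.65e-07), with S100a4 at 2.45 ± 0.35 and S100a6 at 0.47. In G2/M and mitosis 15 of 40 rose (20 adjusted over the list alone), median 0.48 (camera adjusted p = 8.33e-11), with the mitotic kinesin Kif20a at 1.3 ± 0.14, the spindle gene Nusap1 at 0.81, cyclin B1 (Ccnb1) at 0.73 and Prc1 at 0.59. In S phase 4 of 44 rose (10 up and 1 down adjusted over the list alone), median 0.29 (camera adjusted p = 0.000393, adjusted p = 0.242 with an estimated correlation). The 4 were the ribonucleotide reductase subunit Rrm2 (0.98), Cdc6 (0.86), Ccne2 (0.80) and Mcm3 (0.75). In NF-kB and inflammatory genes 2 of 13 rose (3 adjusted over the list alone), median 0.89 (camera adjusted p = 0.00864, adjusted p = 0.0432 with an estimated correlation). They were the chemokine Cxcl5 (3.31 ± 0.70, adjusted p = 0.000787) and the prostaglandin synthase Ptgs2 (2.48 ± 0.78, adjusted p = 0.0362), whose call was lost without library set 1, 4, 5, 8, 9 or 11. In interferon-stimulated genes 2 of 19 rose (2 adjusted over the list alone), Xaf1 (0.81) and Isg20 (1.04, lost without library set 8, 9 or 11), median 0.41 (camera adjusted p = 0.00864, adjusted p = 0.131 with an estimated correlation). With sets summed the calls of Car1, Emp1, S100a6, Cdc6, Mcm3, Ptgs2 and Isg20 were lost.

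**Figure D2:**
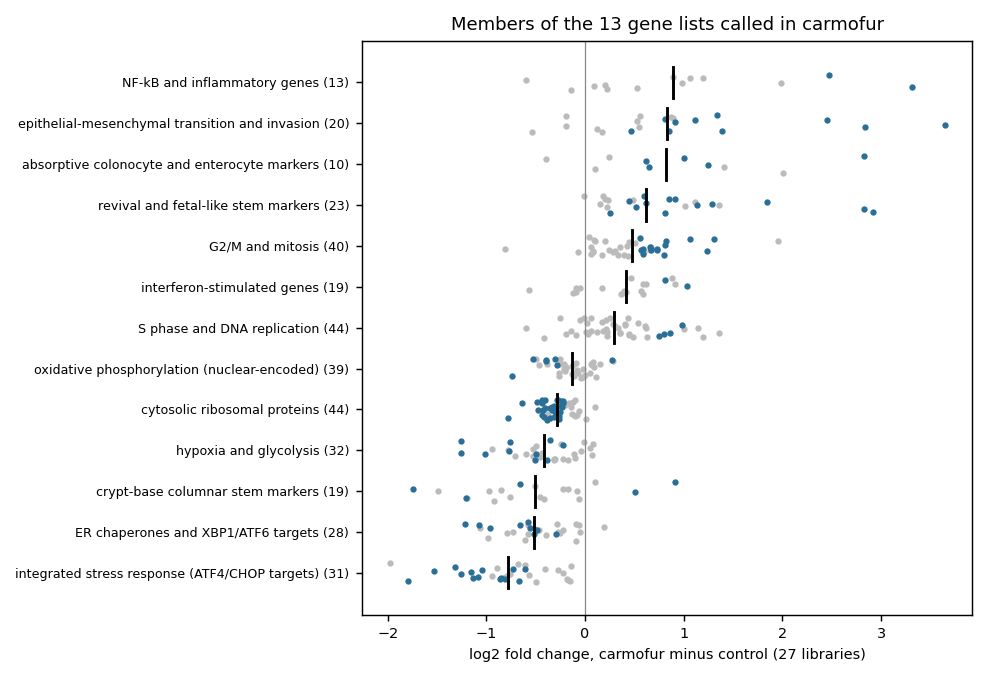
Log2 fold change (carmofur minus control, horizontal axis) of each measured member of 13 gene lists, with the number of members in brackets. Only the lists past an adjusted p of 0.05 by camera are shown, 13 of 31 tested. Blue points passed an adjusted p of 0.05 by edgeR, grey points did not, and black bars are medians. The medians run from -0.78 for the integrated stress response to 0.89 for NF-kB genes, with ribosomal proteins at -0.28 and revival stem markers at 0.62.

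Among genes with a mean of at least 5 CPM and a consistent direction, as the naming rule asks, the largest rises also included the ion transport regulator Fxyd4 (4.68 ± 0.83), the scramblase Plscr2 (4.23 ± 0.69), Spats2l (3.83), the collagenase Mmp13 (3.65), Dmkn (3.59), the serpin Serpinb2 (3.29) and Zfat (3.28), each at or under 1.62 CPM in the controls. Large falls were those of Adprh (-2.01), the receptor Fgfr2 (-1.78), Nt5dc1 (-1.68) and Rfxank (-1.48). Calls were lost without library set 8 (Dmkn), 5 (Mmp13 and Serpinb2), 1, 5 or 11 (Adprh), 3, 5, 9, 11 or 12 (Fgfr2) and 5, 8 or 9 (Rfxank). Sphingolipid and ceramide metabolism did not pass as a list: 3 of 35 rose (3 adjusted over the list alone), and camera gave an adjusted p of 0.361. The 3 were the ceramide synthase Cers5 (1.48 ± 0.42), the sphingomyelin synthase Sgms1 (0.71 ± 0.22) and Sptssa (0.39 ± 0.11). These calls were lost without library sets 1, 4 or 12 (Cers5), 1, 3, 4, 5, 8 or 12 (Sgms1) and 5 or 7 (Sptssa). With sets summed the calls of Dmkn, Mmp13, Serpinb2, Adprh, Rfxank, Cers5, Sgms1 and Sptssa were lost. Asah1, which encodes acid ceramidase, had 405 ± 64.8 and 452 ± 63.2 CPM (0.16 ± 0.09, adjusted p = 0.356). Acer2 (-0.18), Acer3 (0.27), Apc (0.06), Trp53 (-0.12), Myc (0.44), Cpt1a (-0.19) and Plin2 (0.35, adjusted p = 0.0526) did not pass.

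**Figure D3:**
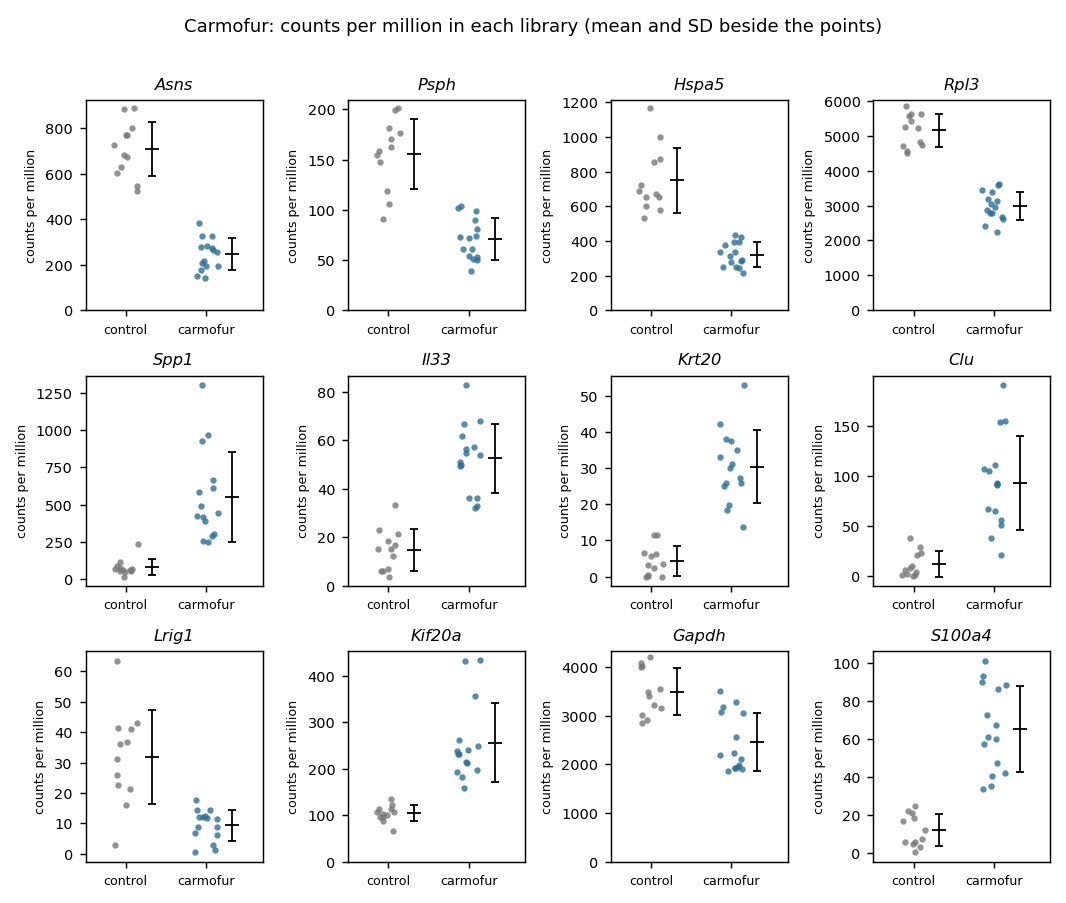
Expression of genes named for carmofur, in TMM-scaled CPM on the vertical axes, per library of 12 controls and 15 treated; points are libraries and bars give the mean ± SD. Asns, Hspa5 and Rpl3 lie lower and Spp1 lies higher in all 15 treated libraries than in any control.

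The remaining lists did not pass camera with carmofur. Those with members past the threshold over all genes were cholesterol biosynthesis (2 up and 3 down of 25, 2 and 5 adjusted over the list alone, list adjusted p = 0.0818), fatty acid synthesis (1 and 1 of 21, 2 and 2, 0.361) and YAP targets (1 up of 19, 2 up, 0.0818). In the same order, the values were, for DNA repair (2 and 1 of 36, 2 and 1, 0.376), ribosome biogenesis (3 and 1 of 39, 3 and 1, 0.611), nucleotide synthesis (2 and 3 of 31, 4 and 3, 0.874). They were, for MAPK feedback (1 and 1 of 26, 2 and 1, 0.376), NRF2 (3 and 3 of 31, 4 and 4, 0.545), lysosome (3 up of 37, 3 up, 0.222). They were, for heat shock (2 and 2 of 17, 2 and 2, 0.874), apoptosis (1 and 1 of 26, 1 and 1, 0.58), goblet markers (1 down of 8, 1 and 1, 0.376) and the genes fixed by name (3 up and 1 down of 15, 4 and 1, 0.11). No member passed over all genes in fatty acid oxidation and PPAR targets (19 measured, 2 up adjusted over the list alone, list adjusted p = 0.142), p53 targets (24, 0 adjusted over the list alone, 0.611), Paneth markers (6, 2 up and 1 down adjusted over the list alone, 0.715) and mitochondrial mRNAs (13, 0 adjusted over the list alone, 0.656). Markers of other cell types were low. The summed level was 31.6 ± 19.3 CPM in controls and 28.1 ± 22.4 CPM with carmofur for 24 mesenchymal genes, and 151 ± 36.5 and 156 ± 71.9 CPM for 30 immune genes. For 21 endothelial and blood genes it was 21.2 ± 7.91 and 30.4 ± 13 CPM. These lists, the enteroendocrine and tuft cell lists, and the replication-dependent histones with carmofur (68.3 ± 29.2 and 93.2 ± 50.8 CPM summed over 16 genes) had fewer than 5 tested members. Of the tuft list Ptgs1 rose (1.8, adjusted p = 0.0362), and no enteroendocrine member passed.

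Mitochondrially encoded transcripts held 5.66% of the counts in carmofur controls and 5.79% with carmofur. The library numbers in the carmofur experiment fall into 3 blocks of 12 numbers, each with controls and treated libraries. Within the blocks these shares were 5.67% and 5.54%, 4.92% and 6.18%, and 6.02% and 5.54%, and in the 3 libraries of set 8 in block 2 they were 6.85% to 7.15%. Within the blocks 234, 512 and 588 genes passed (3 controls against 6 treated, 3 against 6, and 6 against 3). In each block either the controls or the treated libraries come from 1 library set, so these counts include any difference between sets. The list medians within blocks were -0.80, -0.97 and -0.80 for the integrated stress response, -0.40, -0.76 and -0.42 for ER chaperones, -0.26, -0.39 and -0.19 for ribosomal proteins, and 0.44, 0.74 and 0.63 for revival markers. Among the other lists past the threshold, the medians were -0.40, -0.27 and -0.93 for hypoxia and glycolysis, -0.18, -0.20 and -0.02 for oxidative phosphorylation, and -0.52, -0.39 and -0.75 for crypt-base columnar markers. They were 0.59, -0.07 and 0.46 for S phase, 0.72, 0.32 and 0.54 for G2/M, 0.18, 0.52 and 0.17 for interferon-stimulated genes, 1.21, 1.48 and 1.23 for NF-kB genes, 0.36, 1.19 and 0.65 for invasion, and 0.93, 0.73 and 0.55 for absorptive markers.

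The treatments, each against its own controls, were compared gene by gene. Across the 9343 genes tested in both, the log2 fold changes of carmofur and of palmitic acid batch 1 had r = 0.00277 (genes are not independent replicates). Noise in the fold changes weakens r, and the value that related effects would give with this noise was not computed. This r therefore does not show that the effects are unrelated. In all 17 genes passed in both, against 4.94 for independent lists (Fisher's exact test, p = 3.32e-06). Of these, 3 rose in both (1.58 for independent lists), 3 fell in both (0.933) and 11 moved in opposite directions (2.43). The values for independent lists take every gene as equally likely to pass. Abundant genes of low spread pass more easily in both comparisons, so the excess does not by itself show that the treatments act on the same genes. With batch 2 in place of batch 1, 7 genes passed in both: 3 rose, 2 fell and 2 moved in opposite directions. With both batches as 1 group, 19 passed in both: 6 rose, 6 fell and 7 moved in opposite directions. The ER oxidase Ero1a (-0.92 with palmitic acid, -1.26 with carmofur), Hspa5 (-0.58, -1.22) and Pfkp (-0.64, -0.76) fell in both. Tuba1a (0.67, 0.56) and the cornified envelope genes Sprr2a2 (0.90, 0.56) and Sprr2a3 (0.82, 0.45), near-identical copies whose reads may be shared, rose in both. Car1 (-1.02, 1.0), the lysophospholipase Enpp2 (-0.91, 1.24), Ahnak (-0.87, 0.59), Mgat4c (-2.03, 1.21) and Serpinb11 (-0.98, 1.91) fell with palmitic acid and rose with carmofur. Mt2 (0.58, -0.98), Mt4 (0.73, -0.60), the farnesyl diphosphate synthase Fdps (0.50, -0.30), H2az1 (0.44, -0.35), Sypl (0.54, -0.57) and Rps23-ps1 (1.03, -0.22) did the reverse. Of these 11 genes Car1 (-0.10), Mt2 (0.01), Mt4 (-0.08), Fdps (0.08), H2az1 (0.06) and Rps23-ps1 (0.24) were near 0 in batch 2 and did not pass there, and Ahnak and Enpp2 were the 2 that passed. Of these genes only Car1, Hspa5, Pfkp, Mgat4c, Serpinb11, Mt2 and Mt4 fell under the naming rule, and the others were named after their values were seen.

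The difference between the effects was tested in a model of all 35 libraries, in which 97 of 14052 genes passed, 77 higher and 20 lower for carmofur than for palmitic acid. The glutathione transferase Gsta1 (3.52 ± 0.86, adjusted p = 0.0336, edgeR), Il33 (2.55 ± 0.63, 0.0344) and the tetraspanin-like Tm4sf1 (2.54 ± 0.46, 0.00163) had the largest positive differences among genes named by the rule. The metallothioneins Mt2 (-1.55 ± 0.33, 0.00875) and Mt4 (-1.31 ± 0.26, 0.00592) and Rpl22l1 (-1.30 ± 0.32, 0.0344) had the largest negative ones. Of the 97 genes, 89 had passed with carmofur, 9 with palmitic acid and 6 with neither. Of the 11 genes that moved in opposite directions, 7 passed, Enpp2 among them (2.16 ± 0.26, adjusted p = 4.23e-07), while Car1 did not (2.03 ± 0.57, adjusted p = 0.112).

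**Figure D4:**
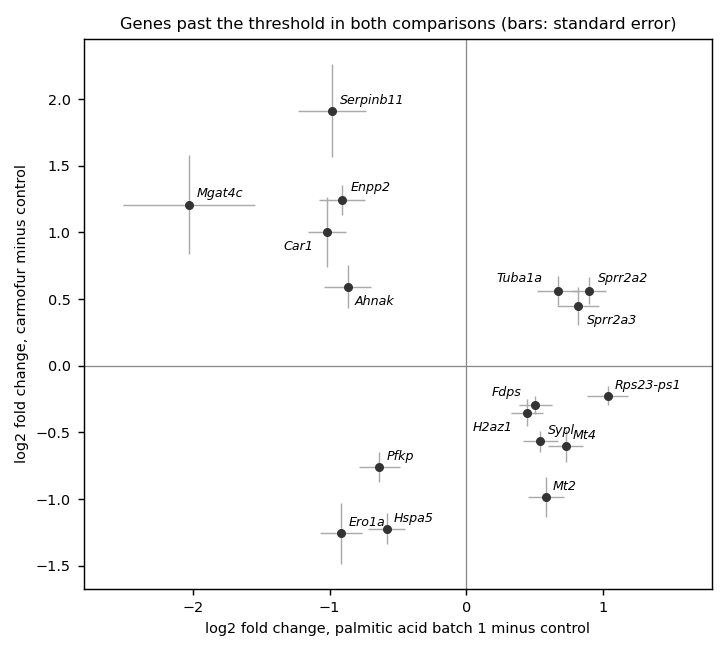
Log2 fold change with palmitic acid batch 1 (horizontal axis) against that with carmofur (vertical axis) for the 17 genes that passed in both comparisons; each point is a gene and bars are standard errors. In 11 genes the signs are opposite, among them Car1 at -1.02 and 1.0 and Enpp2 at -0.91 and 1.24.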

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

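The explanation by the shallow control library and the splits of the difference over library sets and over palmitic acid labels alone were chosen only after the result was seen, and the offsets for length and GC content and the library-size scaling were added after the gene lists were seen. The other tests in this part were chosen before their results.

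Treated batch 2 differed from treated batch 1 in 10 genes by a direct test, with Car1 0.92 log2 units higher in batch 2. This is a difference in level, since no control belongs to a stated batch. The effect of carmofur differed between the blocks of library numbers in 178 genes by the interaction test, with single libraries as replicates. The controls of blocks 1 and 2 and the treated libraries of block 3 each come from 1 library set. A difference between blocks therefore cannot be told from one between sets. The effects of carmofur and palmitic acid batch 1 differed in 97 genes. Of 60 splits of single libraries within both experiments 1, the real one, gave as many, and the highest other gave 6. Of 100 splits of the library sets, summed, and of the palmitic acid libraries, 1 gave as many as the real 91, and the highest other gave 75, with the carmofur labels as they are. These splits also undo the carmofur effect, and 89 of the 97 genes had passed with carmofur, so they say nothing of a difference between the effects. With the carmofur labels kept, 1 of the 20 arrangements of the palmitic acid labels gave as many, the highest other gave 90, and these are too few to exclude chance.

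The first pattern weighed is the 55 genes that passed in palmitic acid batch 1, among them Tff1, Wfdc18, Rnf186, Fgfbp1 and Car1. The real grouping gave 55 genes and the highest other split 3, with 1 of 10 splits giving as many, which are too few splits to exclude chance. Without the shallow control library 36 of the 55 genes still passed in the same direction, and with offsets for length and GC content 43 did, so neither explanation accounts for most of the calls. The biological explanation, the treatment, may account for the rest, but the labels give 1 control group in no stated batch, so a batch difference stays open, and a difference between culture wells or days was not tested.

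The second pattern is the 901 genes that passed with carmofur. Of 100 splits of the libraries 1, the real one, gave as many, and the highest other gave 222. Of 100 splits of the library sets summed, 1 gave as many as the real 334, and the highest other gave 98. Such counts are therefore unlikely from a random division of these libraries or sets. The splits took libraries and sets as exchangeable and did not keep the library blocks, so they show no more than that. With offsets for length and GC content 871 of the 901 genes still passed in the same direction. The treatment may account for these calls, but whether sets are separate cultures is not known.

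The third pattern is the direction of 4 gene lists with carmofur. With the offsets the medians were -0.768 for the integrated stress response, -0.526 for ER chaperones, -0.322 for ribosomal proteins and 0.611 for revival markers, so a length or GC trend does not account for them. The ribosomal median was at most -0.260 under RLE size factors or library-size scaling. The medians of all genes were -0.00797 and 0.0210 under these and 0.00165 under TMM. These scalings were too alike to test whether scaling accounts for that list. The revival median was at least 0.544 without each library set, so no 1 set accounts for the revival list. Mesenchymal or immune cells stay open: 0 of their 10 most abundant markers rose past the threshold, but only Cd14, Cd68 and Vim were tested, and S100a8 went from 0.261 to 7.6 CPM and S100a9 from 0.113 to 2.46 CPM untested. Whether ceramidase inhibition or another action of the compound lies behind the lists was not tested.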

How the results depend on the processing

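With 1 batch 2 library left out the lone library is assumed to vary like the others. Of 2747 values of 145 gene results under alternatives (the batch difference apart), 2442 kept direction and side of the threshold, 231 no longer passed, 44 newly passed and 30 reversed. Asns, Hspa5, Rpl3, Spp1, Clu, Il33 and Krt20 passed with carmofur, and Rnf186 and Fgfbp1 with palmitic acid batch 1, in every alternative. Requiring an absolute log2 fold change of 1 left 24 of 55 genes in palmitic acid batch 1 and 280 of 901 with carmofur, by construction. DESeq2 gave 55 in place of 32 for batch 2 and 204 in place of 97 for the difference, and voom with quality weights 239 for the difference. With no filter 19 genes in place of 10 differed between batches and 3541 passed with carmofur (888 of the 901 among them), and library sets summed gave 334 (287 shared), with 9 samples in place of 27. Leaving out each library gave 21 to 72 genes in batch 1, 23 to 48 in batch 2 and 2 to 14 between batches, and each set 740 to 981 with carmofur. For these counts the cause was not tested beyond the construction named. Palmitic acid lists past the threshold were 3, with an estimated correlation 0 and without control replicate 1 6. Of the lists fixed beforehand, with sets summed only the integrated stress response (0.00872) and ER chaperones (0.0304) passed with an estimated correlation.

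With the replicate block, 42, 28 and 8 genes passed in the palmitic acid comparisons and 818 with carmofur, and 3 and 16 lists. The carmofur block fit left out carmofur 13, 14 and 15, which have no control of the same number. It tested 13518 genes in place of 9992. Deviations from the group mean correlated between same-numbered control and treated libraries at -0.0197 to 0.0217 (batch 1) and -0.0219 to 0.0492 (carmofur). Of these pairs 1 of 3 and 0 of 12 correlated best with each other. Between batch 1 and batch 2 the values were 0.00781 to 0.0092, and 2 of 2 pairs correlated best with each other. Within a group of the carmofur experiment this measure averaged -0.0102 in the same set, -0.036 between sets of a block and -0.102 between blocks. Libraries of a set were thus more alike than libraries of other blocks. The correlation estimated for sets as a correlated group was 0.127. Taking out the group mean lowers values within a group, so they are no scale for those between groups. The measure cannot show whether the numbers pair libraries.

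Signs reversed only in gene results that passed neither as reported nor when reversed, and the cause was not tested. In palmitic acid batch 1 these were Apc with offsets (0.139), Ascl2 with voom weights (0.18) and Lgr5 with batches merged (-0.304). With carmofur they were Apc with voom weights (-0.0859), sets summed (-0.0014), set correlation (-0.085) and without the 3 libraries (-0.113), Cpt1a with sets summed (0.0246) and without the 3 libraries (0.0648), and Trp53 with sets summed (0.00759). Leaving out each library in palmitic acid batch 1 gave Acer2 -0.0369 to 0.569, Apc -0.437 to 0.341, Asah1 -0.0384 to 0.19, Ascl2 -0.739 to 0.669, Cpt1a -0.371 to 0.234 and Myc -0.306 to 0.0159. Leaving out each set with carmofur gave Acer2 -0.347 to 0.00939, Apc -0.0884 to 0.165, Cpt1a -0.307 to 0.00939 and Trp53 -0.499 to 0.0944.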

Other observations

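The tests of cornified epithelium genes and of tRNA synthetases were chosen only after the results were seen, on the same libraries, so they are not independent of them. Cornified and squamous genes were higher with carmofur: 16 of 35 measured members rose and 1, Pkp1, fell, with a median log2 fold change of 0.94 (camera adjusted p = 7.53e-09 over the 2 added lists, adjusted p = 0.00518 with an estimated correlation). The cystatin Csta1 was at 6.40 and the squamous keratins Krt4, Krt13 and Krt14 at 2.14, 3.07 and 2.84. Whether carmofur raises this list as a set stays open, since the list was chosen for genes seen to rise in these libraries. The higher camera adjusted p of single libraries and summed sets was 2.25e-08, and with sets summed the adjusted p was 0.0601 with an estimated correlation.

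Cytosolic tRNA synthetases, several of them ATF4 targets such as Sars, were lower with carmofur: 13 of 20 fell, with a median of -0.54 (camera adjusted p = 1.29e-13, adjusted p = 2.63e-06 with an estimated correlation). The higher camera adjusted p of single libraries and summed sets was 7.53e-12. This is no separate support for an effect on the list, which was chosen after such falls were seen and shares genes with the integrated stress response list. In palmitic acid batch 1 the list had a camera adjusted p of 0.0161 (adjusted p = 0.0684 with an estimated correlation), and in batch 2, also lower, 0.00399 (adjusted p = 0.0456 with an estimated correlation). For the cornified list these were 0.714 in batch 1 and, higher in batch 2, 0.00399 (adjusted p = 0.0856 with an estimated correlation).

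Genes annotated as long non-coding RNA or as unconfirmed transcripts made up 65 of 521 genes that rose with carmofur and 3 of 380 that fell (odds ratio 17.9, Fisher's exact test). They held 1.39 ± 0.0756% of the counts in controls and 2.07 ± 0.459% with carmofur, and all 15 treated libraries lay above the highest control. A permutation test gave an adjusted p of 0.0001 over libraries and 0.0795 over library sets. The share of Malat1, a nuclear long non-coding RNA, was 0.317 ± 0.0944% and 0.484 ± 0.222% (adjusted p = 0.0367 over libraries and 0.438 over sets, permutation test). The 3 libraries of set 8 had the highest values of long non-coding transcripts (2.66% to 3.09%), of mitochondrial transcripts (6.85% to 7.15%) and of the 10 most abundant genes (11.2% to 12.1%). This comparison was also made after the gene lists were seen, a prediction written for it was set aside once its result was known, and no explanation is weighed here. With the offsets for length and GC content the odds ratio was 14.5. The shares in the palmitic acid experiment were 2.04% in controls, 1.65% in batch 1 and 2.04% in batch 2.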
